A study of Mus musculus with 93 samples.

How the data were processed

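RNA was sequenced from mouse embryonic stem cells of the R1 line, grown in serum medium with leukaemia inhibitory factor. Of the 93 samples of the series, 12 RNA-seq libraries were analysed, and the chromatin assays of the series were not analysed here. Per the labels, the libraries form 4 groups of 3 replicates: wild type and Ring1b I53A cells in set 1, and wild type and H1b/c/d/e quadruple-knockout (QKO) cells in set 2. Nothing in the labels says whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. All pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom between 2.25 and 29.7, so each library was counted once.

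The authors deposited 1 table of raw counts per library, with whole numbers that sum to a different total in each. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the Illumina TruSeq procedure. Per the file headers, fragments were counted with featureCounts version 1.6.3 in paired-end mode by gene name, on the GENCODE annotation of NCBIM37 (mm9). Per the file headers, no option for strand, for fragments with several alignments or for fragments over several genes was set. Reads from overlapping or antisense genes can therefore be lost or not told apart. Near-identical gene copies such as the Zscan4 family can lose reads or hold reads of uncertain origin. Overlaps named below were taken over whole gene spans with introns, so an overlap need not touch counted reads. The submitters' processing notes name HISAT2, featureCounts, DESeq2, Bowtie2 and SAMtools without versions, and the builds mm9 and dm6. Per the file headers, the alignments counted for set 1 carry TopHat and unique in their names, while those of set 2 carry neither, so the alignments of the sets were not named alike. The notes are the same for both sets and so do not settle which aligner was used for each. The RNA selection is not given in the sources used here. Each table lists 33924 gene names, of which 99 lie on more than 1 chromosome. The deposited names were used as they stand, with symbols of the older nomenclature such as H1f0 and Hist1h1c.

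Depth ranged from 12585621 to 23378930 counts per library. Replicate 3 of both set 1 groups was the shallowest of its group, with 13205478 counts for wild type and 12585621 for I53A. Their deposited tables also follow another naming style than those of replicates 1 and 2, which was treated as a possible batch. Counts carry no molecular identifiers, so counting intervals and floors cover counting error only.

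Counts were normalised by TMM and tested with edgeR's quasi-likelihood test with robust dispersion (edgeR version 4.0.16, R version 4.3.3), after filterByExpr with its defaults. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The spread was taken from the 6 libraries of each genotype comparison. The difference between the effects, I53A minus its wild type less QKO minus its wild type, was tested as an interaction over all 12 libraries, and the wild type groups of both sets were compared in that fit. CPM values, that is counts relative to the library total, were computed from the deposited counts with TMM-scaled library sizes and are given as mean ± SD with n = 3. For a comparison within a set the scaling was taken over its 6 libraries. For values per library of the targeted genes, and for levels in both sets side by side, it was taken over all 12, so values of the same gene differ between these scalings. Log2 fold changes computed from the deposited counts are given ± SE. For a gene at 0 in all libraries of a group, the fold is a lower bound against a floor of 3 counts over the group, and for 1 to 3 counts the ratio of summed counts is given with its exact 95% interval.

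For sets of genes, 31 lists were fixed before the data were examined. They cover chromatin proteins, developmental regulators, lineage markers, imprinted and germline genes, stress and metabolic pathways, and markers of fibroblast feeder cells. Lists with at least 3 tested genes, and each of chromosomes 1 to 19 and X, were tested with camera in limma version 3.58.1 at a preset correlation of 0.01. Camera with an estimated correlation and the rotation test fry were run beside it. Overlap of calls was tested with Fisher's exact test per direction.

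Genes named in the text follow a rule fixed at the same time. It takes the targeted genes, the 8 largest increases and 8 largest decreases per comparison, 4 members of each called list and up to 2 of each other list. For the largest changes it asked for an adjusted p under 0.05, groups that do not overlap and at least 1 CPM in the higher group. Provisional names (such as Gm numbers, Rik clones, small RNAs in any letter case, pseudogenes and clone identifiers) were left out. The difference between effects takes the 5 largest in each direction, without the condition on overlap. Not every gene that the rule takes is named in the text. Other genes named in the text were chosen after their values were seen: the list members Srgn, Pdgfra, Foxa2, Hnf4a, Mirg, Dlk1, Peg10, Igf2, Grb10, Sox7 and Usp9y in set 1, Klf2, Dppa3, Nanog, Sox2, Pou5f1, Magel2, Igf2, Cubn, Srgn, Gata4 and Gata6 in set 2, Gapdh, Rpl31, Rpl7 and Rpl8 between sets, and the further endoderm markers.

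The replicate numbers of set 1 were checked by correlating each library's deviations from its group mean over 15536 genes. Same-numbered libraries correlated at 0.229, 0.258 and 0.491, all above the 0.1 set as the condition, which was thus met. Wild type 1 with I53A 2 gave 0.218 and wild type 2 with I53A 1 gave 0.241, so numbers 1 and 2 are not told apart. Replicate 3 against the others gave -0.323 to -0.361, so the pairing rests mainly on replicate 3. The deposited tables of I53A replicates 1 and 2 carry each other's number, and the numbers of the sample labels were used. The fit with the replicate number as a block is therefore given where it changes a call or moves a count by over 1.5 times.

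The edgeR and DESeq2 steps were tested on simulated data in which 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. In the simulation of I53A against wild type (15267 genes), edgeR recovered 26.9% of the genes changed 1.5-fold, 71.6% of those changed 2-fold and 93.9% of those changed 4-fold, with 13 unchanged genes called. For QKO against wild type (15202 genes) the shares were 74.6%, 89.6% and 95.5%, with 9 unchanged genes called. For the difference between effects (16071 genes) they were 22.4%, 50.7% and 77.3%, with 4 unchanged genes called. Far fewer genes were changed in the simulations than were called in the data, so these shares need not carry over. Camera was run on separate simulated data, with the pluripotency list raised by 0.5 and chromosome 8 lowered by 0.3 on the log2 scale. It called both in every comparison, and 1 other list for the difference between effects. Genes were drawn independently there, so correlation between genes was not tested.

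Alternatives tried were DESeq2's size factors, scaling by library size only, no filter, a filter of 1 CPM in 3 libraries, DESeq2 version 1.42.0, a replicate block, a gene-length offset, both together, a log2 fold change threshold of 1, a term for the naming style, a spread shared over all 12 libraries and leaving out each library in turn. After the data were seen, fits on replicates 1 and 2 of set 1 only, a block with I53A replicates 1 and 2 exchanged and fits without chromosomes that shifted as a whole were added.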

Results

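Gene expression was measured by RNA-seq in mouse R1 embryonic stem cells in 4 groups of 3 libraries. Set 1 compared wild type cells with cells carrying the I53A point mutation of Ring1b, the subunit through which Polycomb repressive complex 1 (PRC1) places ubiquitin on histone H2A. Set 2 compared wild type cells with cells labelled H1b/c/d/e quadruple knockout (QKO), a label that names linker histones, the proteins that bind between nucleosomes and compact chromatin. Total counts for replicates 1 to 3 of set 1 were 17845898, 18045900 and 13205478 in wild type and 17934667, 17768576 and 12585621 in I53A. In set 2 they were 17438737, 18400587 and 21652513 in wild type and 23378930, 15912394 and 21112985 in the libraries labelled QKO. Each library detected between 19419 and 21519 genes with at least 1 count.

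The targeted genes were examined first. Rnf2, the gene of Ring1b, lies on the minus strand of chromosome 1 from 153316536 to 153347953 (mm9, the build of all coordinates here). With scaling over all 12 libraries its CPM values were 183, 180 and 164 in the wild type replicates of set 1 and 93.7, 92.1 and 79.3 in the I53A replicates. A point mutation need not change the amount of RNA, so these values do not check the I53A label. In set 2, Rnf2 stood at 221, 215 and 200 CPM in wild type and at 182, 187 and 185 CPM in the libraries labelled QKO.

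None of the 4 linker histone genes that the QKO label names was lower in the libraries so labelled, by edgeR's test. Hist1h1b (chromosome 13, 21871752 to 21872494) had 4, 9 and 2 counts in the wild type replicates and 62, 53 and 72 counts in those labelled QKO. Hist1h1c had 143, 173 and 205 counts against 174, 129 and 202, and Hist1h1d had 10, 3 and 14 counts against 15, 7 and 5. Hist1h1e had 6, 0 and 2 counts against 12, 3 and 7, too few to be tested. These transcripts do not bear out the label, so the groups are called libraries labelled QKO. Apart from Hist1h1c, these genes had at most 14 counts in any wild type library, so a fall would be hard to see in them. Which part of each gene the knockout removes is not given in the sources used here, and reads from outside that part would check nothing.

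**Figure D1:**
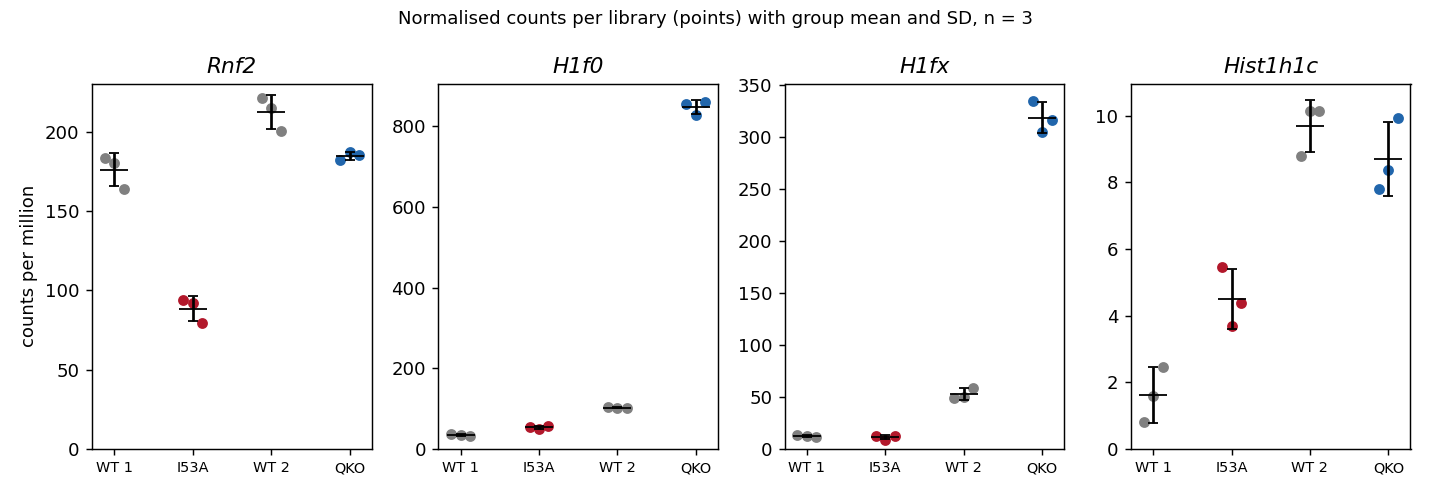
CPM of Rnf2, H1f0, H1fx and Hist1h1c, scaled over all 12 libraries, in each library (points), with the group mean (bar) and SD (n = 3) for wild type of set 1, I53A, wild type of set 2 and libraries labelled QKO. Rnf2 was lower in I53A (79.3 to 93.7 CPM) than in its wild type (164 to 183 CPM), and H1f0 was higher in the libraries labelled QKO (828 to 859 CPM) than in their wild type (100.4 to 103.4 CPM).

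Comparing I53A with wild type asks which genes change when Ring1b carries a mutation in its catalytic part. Genes of primitive endoderm, a yolk sac lineage of the early embryo, had the highest median rise of the fixed lists. Cubn, an endocytic receptor of the visceral endoderm (chromosome 2, 13197965 to 13413551), rose from 1.41 ± 0.539 to 314 ± 10.3 CPM (mean ± SD, n = 3, scaled over the 6 libraries of the set as in the rest of this comparison). Dab2, an adaptor of the same uptake pathway, rose from 4.79 ± 0.303 to 192 ± 2.10 CPM. The maternally expressed non-coding RNAs Meg3 and Rian of the imprinted Dlk1-Dio3 region on chromosome 12 fell, Meg3 from 58.9 ± 6.66 to 0.930 ± 0.134 CPM and Rian from 73.4 ± 12.8 to 0.758 ± 0.0415 CPM. The log2 fold changes (± SE) were 7.76 ± 0.19 for Cubn, 5.32 ± 0.09 for Dab2, -5.97 ± 0.16 for Meg3 and -6.58 ± 0.20 for Rian, with edgeR adjusted p = 1.9e-07, 4.2e-08, 2.9e-07 and 4.9e-07. With the scaling of the set, Rnf2 RNA fell from 186.28 ± 7.72 to 93.2 ± 6.58 CPM (log2 fold change -0.998 ± 0.078, edgeR adjusted p = 5.6e-05).

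Of 15536 genes tested, edgeR called 2808 higher and 2704 lower in I53A, and 1307 of the former and 561 of the latter changed at least 2-fold. Among all tested genes, 7677 (49.4%) had groups that did not overlap, where chance gives 10%. With the replicate numbers as a block 8798 genes were called. The replicate 3 tables of both groups follow another naming style than the rest. Fitting only replicates 1 and 2 called 8343 genes, and of 8242 of these also measured in the replicate 3 pair, 94.4% had the same sign there.

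Apart from Cubn, the largest increases belonged to genes hardly seen in wild type. Tcfec, a transcription factor related to Mitf, had 0 counts in wild type and was at least 92.3-fold higher in I53A, against a floor of 3 counts over the group. By the same measure the peptidase gene Enpep was at least 66.6-fold higher, the galectin gene Lgals2 at least 51.4-fold, Timd2 at least 50.4-fold, Tmem72 at least 24.96-fold and the glucuronosyltransferase gene Ugt2b34 at least 17.9-fold. Lgals2 overlaps Cdc42ep1, so its reads are uncertain. Dkk1, a secreted inhibitor of Wnt signalling, had 1 count in wild type and 318 in I53A, a ratio of 320.1 (95% counting interval 57.0 to 12682.5). The other large decreases included Rtl1, an imprinted gene of the Meg3 region, with 81 counts in wild type and 2 in I53A (ratio of wild type to I53A 40.2, interval 10.8 to 338). Slfn9 fell from 21.7 ± 1.51 to 0.770 ± 0.310 CPM, Nkx6-3, a homeobox gene, from 17.7 ± 1.57 to 1.51 ± 0.173 CPM, and Nrp2, a semaphorin receptor gene, from 67.8 ± 3.62 to 5.91 ± 1.43 CPM (log2 fold changes -4.78 ± 0.23, -3.53 ± 0.16 and -3.50 ± 0.16). Dnajc5g and Spatc1 fell by 3.88 and 3.55 on the log2 scale. Meg3, Rian and Rtl1 overlap microRNA genes, and Slfn9 has close paralogs, so their reads are partly uncertain.

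The fixed lists show which groups moved together. Counts of members are over all genes tested, and where they differ the counts adjusted over the list alone follow. Of 20 tested primitive endoderm genes 19 rose and 1 fell (median log2 fold change 4.38, camera adjusted p = 1.2e-95, and 0.00864 with an estimated correlation). The rise included the endoderm transcription factors Gata4 (4.40), Gata6 (5.25), Sox17 (5.08) and Foxa2 (5.62), and the basement membrane genes Col4a1 (4.30), Col4a2 (4.61) and Lama1 (3.39). Srgn (6.03) and the growth factor receptor gene Pdgfra (4.35) rose too, while Hnf4a, a regulator of visceral endoderm and liver, fell by 1.35 on the log2 scale. Col4a1 and Col4a2 overlap each other at their start, so a share of their reads is uncertain. Of 39 Hox genes in the annotation, the regulators of position along the body axis, 20 passed the filter and were tested. Of these 18 rose (19 adjusted over the list alone) and none fell, with a median of 3.43, camera adjusted p = 3.2e-11 and adjusted p = 0.0172 with an estimated correlation. A gene with next to no reads in wild type passes the filter only if I53A reads lift it. The direction of such members is therefore set by the filter. Hoxa7 rose by 4.75 and Hoxb13 by 3.76 on the log2 scale, and Hoxc9 went from 3 to 67 counts (ratio 22.5, interval 7.37 to 112). Of 24 germline genes 20 rose and 1 fell (2 fell adjusted over the list alone), with a median of 1.47, camera adjusted p = 4.8e-22 and adjusted p = 0.0145 with an estimated correlation. They included Mael (2.94), Tdrkh (2.50) and Mov10l1 (1.41), which act in transposon silencing by piRNA, and Syce1 (1.68) of the synaptonemal complex. Of 23 fibroblast genes in the annotation, listed as markers of feeder cells, 15 passed the filter, with the same limit as for Hox genes. Of these 12 rose and none fell (13 and 1 adjusted over the list alone), with a median of 1.26, camera adjusted p = 2.9e-07 and adjusted p = 0.0340 with an estimated correlation. Col1a2 (3.94) and Bgn (3.79) encode matrix proteins, and Pdgfrb (1.44) and Thy1 (1.02) surface proteins.

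Further lists were called higher at camera's preset correlation but not with an estimated correlation. All 11 two-cell-like genes, which mark a rare state that resembles the early cleavage embryo, rose (median 3.38, camera adjusted p = 2.2e-29, and adjusted p = 0.0665 with an estimated correlation). Zscan4d rose from 18.5 ± 3.98 to 193 ± 19.1 CPM and Dub1 from 6.70 ± 0.556 to 117 ± 8.97 CPM, and Zscan4b (3.53) and Tdpoz4 (3.20) rose with them. These genes have near-identical copies, so single members are uncertain. Of 111 developmental transcription factors in the annotation 59 passed the filter, with the same limit as for Hox genes. Of these 38 rose and 2 fell (41 and 3 adjusted over the list alone), with a median of 1.94, camera adjusted p = 9.2e-17 and adjusted p = 0.0749 with an estimated correlation. Tbx15, a limb and skin regulator, rose by 4.00 on the log2 scale, and Sox17, Gata4, Gata6, Foxa2 and Sox7 belong both to this list and to that of primitive endoderm.

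Markers of other lineages also rose, with the same limit as for Hox genes. The annotation holds 16 trophoblast, 19 mesoderm, 19 neural, 35 developmental signalling and 15 primed epiblast genes of these lists, and the numbers tested follow. Camera called trophoblast genes (6 rose and 1 fell of 11, median 0.72, adjusted p = 0.000589, and adjusted p = 0.188 with an estimated correlation), among them the keratin genes Krt18 (1.82) and Krt8 (1.65). It called mesoderm genes (7 of 12 rose and none fell, median 1.01, adjusted p = 0.00134, and adjusted p = 0.137 with an estimated correlation), such as the endothelial receptor gene Kdr (2.74), Hand1 (2.76) and Cdx1 (1.96). Of 13 neural genes 7 rose and 1 fell (median 0.59, camera adjusted p = 0.00739, and adjusted p = 0.188 with an estimated correlation), with Nes (1.52) and Crabp2 (2.00) as examples and 1 count against 63 for Zic1 (ratio 63.4, interval 10.98 to 2544). Of 24 developmental signalling genes 12 rose and 4 fell (14 and 5 adjusted over the list alone), with a median of 0.78, camera adjusted p = 0.00635 and adjusted p = 0.295 with an estimated correlation. Fgf10 (3.06) and the TGF-beta family genes Inhbb (0.79) and Nodal (0.77) rose, and Bmp2, with 1 count in wild type, was higher in I53A at a ratio of counts of 104 (interval 18.2 to 4134). Of 14 primed epiblast genes 8 rose and 3 fell (9 and 3 adjusted over the list alone), including Lef1 (4.08), Sox3 (1.64), Cldn6 (1.41) and Dusp6 (0.94), with a median of 0.34, camera adjusted p = 0.0366 and adjusted p = 0.516 with an estimated correlation. Camera lost the primed epiblast call without wild type replicate 1 (adjusted p = 0.0632), wild type replicate 2 (0.0820) or I53A replicate 3 (0.0506). The neural call was lost with the replicate block (camera adjusted p = 0.0680) and on replicates 1 and 2 only (0.0660).

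Glycolysis and hypoxia genes had a small median rise, with 10 of 24 higher and 1 lower (median 0.29, camera adjusted p = 0.00134, and adjusted p = 0.137 with an estimated correlation). The strongest were P4ha1 (1.91) and P4ha2 (2.47), which encode collagen prolyl hydroxylases, beside Vegfa (0.87) and the glycolytic enzyme gene Pfkl (0.67). Of 63 replication-dependent core histone genes in the annotation 14 passed the filter, with the same limit as for Hox genes. Of these 5 rose and none fell (median 0.93, camera adjusted p = 0.0203, and adjusted p = 0.303 with an estimated correlation), including Hist2h2bb (3.77), Hist1h4i (2.33), Hist1h2ah (2.10) and Hist1h2bc (1.74). Camera lost this call with the replicate block (adjusted p = 0.0983), on replicates 1 and 2 only (0.0926) and without wild type replicate 1 (0.0531), wild type replicate 2 (0.0816) or I53A replicate 3 (0.0805). Y-linked genes were the list called lower, with 4 of 6 lower and 1 higher (median -1.23, camera adjusted p = 0.000655, and adjusted p = 0.162 with an estimated correlation). Uty (-2.14), Zfy1 (-2.22), Ddx3y (-1.53) and Eif2s3y (-0.72) fell, and Usp9y (3.17) rose.

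Camera did not call the other 17 lists, although single members changed. Of 27 pluripotency genes 4 rose and 11 fell (median -0.27, camera adjusted p = 0.0574), including Tet2 (-0.68) and Esrrb (-0.60). Camera called this list lower with the replicate block (adjusted p = 0.00523), on replicates 1 and 2 only (0.00544) and without wild type replicate 1 (0.0484) or wild type replicate 2 (0.0343). Of 18 mitochondrially encoded genes 8 rose and none fell (median 0.64, camera adjusted p = 0.0510), with mt-Nd1 at 0.60. Mitochondrial genes took 3.35%, 3.52% and 3.36% of the counts in the wild type replicates and 4.06%, 4.26% and 4.40% in those of I53A. Camera called these higher with the replicate block (adjusted p = 0.00119), on replicates 1 and 2 only (0.000485), with a filter of 1 CPM in 3 libraries (0.0390) and without wild type replicate 3 (0.00902), I53A replicate 1 (0.0296) or I53A replicate 2 (0.0246). Among 31 imprinted genes 12 rose and 7 fell (13 and 7 adjusted over the list alone, median 0.20, mean -0.20, camera direction up, adjusted p = 0.677). Besides Meg3, Rian, Rtl1 and the neighbouring Mirg (-6.03), which fell, Dlk1 (2.37), Peg10 (2.06), Igf2 (2.86) and Grb10 (1.87) rose. Mirg and the members that rose were picked after their values were seen, and changes by parental origin were not tested.

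Among chromatin genes, 5 of 13 canonical PRC1 subunits rose and 1 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.257), with Phc2 at 0.89. Of 18 variant PRC1 subunits 5 rose and 2 fell (camera adjusted p = 0.308), including E2f6 (1.08) and Pcgf5 (1.23). Of 12 PRC2 subunits 3 rose and 1 fell (median 0.13, mean -0.02, camera direction down, adjusted p = 0.771), with Jarid2 at 0.77 and Phf19 at -2.54. Linker histone genes had 2 of 4 higher (3 adjusted over the list alone, camera adjusted p = 0.252), namely H1f0 (0.65) and Hist1h1c (1.49). EdgeR lost the call of Hist1h1c without wild type replicate 2 (adjusted p = 0.0552) or I53A replicate 1 (0.0722). Of 9 replacement histone genes only H2afy2, a macroH2A gene that overlaps Aifm2, changed (-1.14, camera adjusted p = 0.606 for the list). Of 7 H2A deubiquitinase genes 2 fell and none rose (1 rose adjusted over the list alone, camera adjusted p = 0.606). They were Asxl2 (-0.33) and Usp21 (-0.48), and edgeR lost the call of Usp21 without wild type replicate 1 (adjusted p = 0.0512), I53A replicate 1 (0.0853) or I53A replicate 2 (0.0848).

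Stress and growth lists were mixed. Interferon-stimulated genes had 11 of 24 higher and 4 lower (camera adjusted p = 0.129), among them Gbp2 (3.86) and H2-D1 (1.05). Amino acid and unfolded protein response genes had 2 of 19 higher and 8 lower (camera adjusted p = 0.184), among them Ddit3 (-1.49) and Slc3a2 (-0.82). Immediate early genes had 4 of 13 higher and 5 lower (6 lower adjusted over the list alone, camera adjusted p = 0.457), with Egr1 at -2.24 and Atf3 at 1.88. Cholesterol synthesis genes had 4 of 21 higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.457), with Insig1 at 0.64 and Sc4mol at -0.69. Heat shock genes had 3 of 11 higher and 2 lower (camera adjusted p = 0.606), with Hsph1 at 0.90 and Hsp90aa1 at -0.47. Cell cycle inhibitor genes had 1 of 10 higher, Cdkn1c (2.27), and 4 lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.606), including Rbl2 (-1.04). p53 target genes had 5 of 22 higher and 1 lower (median -0.08, mean 0.03, camera direction up, adjusted p = 0.677), with Plk2 at 0.69 and Ccng1 at 0.50. Ribosomal protein genes had 3 of 82 higher and 2 lower (none adjusted over the list alone, camera adjusted p = 0.606). Among them edgeR lost the call of Rpl27a (0.38) without wild type replicate 1 (adjusted p = 0.0597) or I53A replicate 2 (0.0529). It lost that of Rpl8 (-0.26) without wild type replicate 1 (adjusted p = 0.0879), wild type replicate 2 (0.0660), I53A replicate 1 (0.0543) or I53A replicate 2 (0.0718).

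Comparing the libraries labelled QKO with their wild type asks which genes differ where linker histones are removed, per the label. Other linker histone genes, not named in the label, rose most clearly. H1f0, the linker histone of differentiated cells (chromosome 15, 78859152 to 78859689), rose from 95.9 ± 1.73 to 808.66 ± 12.4 CPM (n = 3, scaled over the 6 libraries of the set as in the rest of this comparison). H1fx rose from 49.3 ± 5.19 to 303.88 ± 13.5 CPM, and Hist1h1t, the testis form, went from 1 to 144 counts (ratio 135, interval 23.8 to 5358). The log2 fold changes were 3.08 ± 0.04 for H1f0 and 2.62 ± 0.05 for H1fx, with edgeR adjusted p = 1.7e-49 and 3.3e-32. Of the genes the label names, Hist1h1b rose from 0.274 ± 0.205 to 3.104 ± 0.396 CPM (log2 fold change 3.52 ± 0.37, edgeR adjusted p = 5.5e-12). Hist1h1c (9.11 ± 0.706 and 8.30 ± 1.04 CPM, edgeR adjusted p = 0.361) and Hist1h1d (0.465 ± 0.262 and 0.437 ± 0.203 CPM, adjusted p = 0.888) were not called.

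Of 15439 genes tested, edgeR called 4430 higher and 4473 lower in the libraries labelled QKO, with 1325 and 516 changed at least 2-fold. Groups did not overlap for 9488 genes (61.5%, where chance gives 10%). The H1 transcripts did not bear out the label, but apart from Hist1h1c they had too few wild type counts for a fall to be seen easily. The label was thus neither borne out nor refuted, which limits every direction drawn from this comparison.

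The largest increases were again in genes at 0 in wild type. Lgi1, a secreted neuronal protein gene, was at least 81.4-fold higher, Maml2, a Notch coactivator gene, at least 28.2-fold, Spock3 at least 20.2-fold, Slfn3 at least 19.9-fold and the kinase gene Prkg1 at least 19.02-fold. C1rb went from 1 to 156 counts (ratio 146, interval 25.8 to 5802) and Slc6a13 from 1 to 79 counts (ratio 73.9, interval 12.9 to 2956). C1rb overlaps other complement genes, Prkg1 overlaps Cstf2t and Slfn3 has paralogs, so their reads are uncertain. Nkx6-3 fell from 4.84 ± 0.670 to 0.405 ± 0.0819 CPM and Aldh1b1, an aldehyde dehydrogenase gene, from 11.6 ± 1.12 to 1.94 ± 0.20 CPM. On the log2 scale Nkx6-3 fell by 3.59, Fkbp6 by 3.44, Mmp23 by 2.79, Vax2 by 2.76, Aldh1b1 by 2.59, Rgl3 by 2.52 and Serpinb6c by 2.42.

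Linker histone genes formed the list with the lowest p, with 4 of 7 higher and none lower (median 2.62, camera adjusted p = 7.5e-17, and 0.0253 with an estimated correlation). All 8 tested two-cell-like genes rose (median 4.92, camera adjusted p = 1.3e-11, and adjusted p = 0.0881 with an estimated correlation). In this and other lists, members with next to no reads in wild type passed the filter only through the libraries labelled QKO. The direction of such members is set by the filter. Zscan4d rose from 0.395 ± 0.192 to 15.8 ± 2.29 CPM, and the copies Zscan4c (5.01), Zscan4e (5.00) and Zscan4f (5.65), whose reads are uncertain, rose with it. Of 22 cholesterol synthesis genes 18 fell and 1 rose (18 and 3 adjusted over the list alone), with a median of -0.33, camera adjusted p = 4.6e-06 and adjusted p = 0.0881 with an estimated correlation. They included the enzyme genes Pmvk (-0.96) and Mvd (-0.75) and the cholesterol carrier gene Stard4 (-0.64). Of 23 germline genes 18 rose and 3 fell (median 0.56, camera adjusted p = 3.8e-05, and adjusted p = 0.280 with an estimated correlation), with the meiotic genes Syce1 (1.44) and Smc1b (1.32), the testis bromodomain gene Brdt (1.91) and Tuba3a (1.32). Of 27 pluripotency genes 15 rose and 8 fell (median 0.16, camera adjusted p = 0.00136, and adjusted p = 0.327 with an estimated correlation). Dnmt3l, which overlaps Aire, rose from 36.8 ± 2.53 to 119 ± 0.624 CPM, and Klf2 (1.06), Dppa3 (1.00), Zfp42 (0.86), Dppa2 (0.82), Tbx3 (0.73) and Nanog (0.45) rose as well. Sox2 (0.16) and Pou5f1 (0.14), core factors of the pluripotent state, rose by less. Of 11 fibroblast genes 7 rose and none fell (median 0.85, camera adjusted p = 0.00136, and adjusted p = 0.235 with an estimated correlation), with Col1a2 (4.83), Fbn1 (1.42), Col5a1 (1.13) and Thy1 (0.85). Of 9 neural genes 5 rose and 1 fell (2 fell adjusted over the list alone), with a median of 0.33, camera adjusted p = 0.0328 and adjusted p = 0.280 with an estimated correlation. Nes (1.26), Crabp1 (0.84), Tubb3 (0.83) and Stmn2 (0.33) rose.

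Camera did not call the other 23 tested lists. Of 23 core histone genes 16 rose and 1 fell (camera adjusted p = 0.0733), with Hist1h3g at 1.41. Of 17 primitive endoderm genes 10 rose and 2 fell (median 0.71, camera adjusted p = 0.0723), including Srgn (3.29), Cubn (2.32), Hnf4a (2.04) and Sparc (0.71), while Gata4 (-0.56) and Gata6 (-0.26) were not called. Of 39 Hox genes only 6 passed the filter, and of these 4 fell (5 adjusted over the list alone) and none rose (median -1.56, camera adjusted p = 0.0902). Hoxc13 fell by 1.94 on the log2 scale. Glycolysis and hypoxia genes had 10 of 24 higher and 12 lower (camera adjusted p = 0.0723), with Egln3 at -1.86 and the glucose transporter gene Slc2a1 at -1.05. Replacement histone genes had 1 of 9 higher, H3f3b (0.63), and 7 lower, including H2afy2 (-1.65, camera adjusted p = 0.0723 for the list). Camera called replacement histones lower without wild type replicate 1 (adjusted p = 0.0413) or 2 (0.0409), and primitive endoderm higher without wild type replicate 1 (0.0496) or QKO replicate 2 (0.0492). It called glycolysis and hypoxia genes lower without wild type replicate 2 (adjusted p = 0.0243), wild type replicate 3 (0.0312) or QKO replicate 3 (0.0417). Without chromosome 14, core histones (camera adjusted p = 0.0458), primitive endoderm (0.0291) and glycolysis genes (0.0357) were called.

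Developmental regulators moved both ways. Developmental transcription factors had 9 of 32 higher and 9 lower (median -0.21, mean -0.05, camera direction up, adjusted p = 0.971), with En2 at 2.09 and Pou4f1 at 1.70. Developmental signalling genes had 11 of 19 higher and 5 lower (11 and 6 adjusted over the list alone, median 0.41, mean 0.34, camera direction down, adjusted p = 0.537). The Nodal inhibitor genes Lefty2 (181 ± 7.73 to 49.6 ± 1.61 CPM) and Lefty1 (-1.39) fell. Primed epiblast genes had 6 of 14 higher and 7 lower (median -0.21, mean 0.12, camera direction up, adjusted p = 0.533), with Etv5 at 0.96 and Dnmt3a at 0.67. Mesoderm genes had 1 of 6 higher, Cdx1 (0.44), and 3 lower, including Eomes (-0.97, camera adjusted p = 0.466 for the list). Trophoblast genes had 3 of 9 higher and 4 lower (median -0.22, mean 0.08, camera direction down, adjusted p = 0.855), with Lgals3 at 2.25 and Krt8 at -1.18. Imprinted genes had 12 of 27 higher and 7 lower (camera adjusted p = 0.423), with Magel2 at 3.06, Igf2 at 1.92, Peg3 at 1.09 and Grb10 at -1.04.

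Polycomb genes moved both ways. Of 13 canonical PRC1 subunits 1 rose and 9 fell (10 fell adjusted over the list alone, camera adjusted p = 0.106), among them Ring1 (-0.68) and Phc3 (-0.44). Variant PRC1 subunits had 7 of 18 higher and 5 lower (camera adjusted p = 0.647), with Bcorl1 at 1.71. PRC2 subunits had 4 of 12 higher and 5 lower (median -0.09, mean -0.04, camera direction up, adjusted p = 0.926), with Aebp2 at 0.60. H2A deubiquitinase genes had 5 of 7 higher and 2 lower (camera adjusted p = 0.423), with Bap1 at 0.46.

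The remaining lists cover stress and growth. Heat shock genes had 8 of 11 higher and 2 lower (camera adjusted p = 0.106), with Hspb1 at 0.42. Immediate early genes had 1 of 12 higher and 4 lower (camera adjusted p = 0.276), with Dusp1 at -1.16. Interferon-stimulated genes had 10 of 21 higher and 6 lower (camera adjusted p = 0.364), with Ddx58 at 0.97 and Stat2 at -0.63. Amino acid and unfolded protein response genes had 4 of 20 higher and 6 lower (camera adjusted p = 0.364), with Hspa5 at 0.46 and Ddit4 at -1.10. Ribosomal protein genes had 10 of 82 higher and 26 lower (8 and 26 adjusted over the list alone, camera adjusted p = 0.423), with the retrogene Rpl10l at 1.70 and Rpl15 at 0.45. Mitochondrially encoded genes had 7 of 23 higher and 3 lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.423), with mt-Cytb at 0.43 and mt-Nd4 at 0.36. EdgeR lost the call of mt-Nd4 with the spread shared over all 12 libraries (adjusted p = 0.0843). p53 target genes had 7 of 21 higher and 10 lower (7 and 11 adjusted over the list alone, camera adjusted p = 0.616), with Plk2 at 1.08 and Btg2 at -0.67. Cell cycle inhibitor genes had 2 of 9 higher and 3 lower (camera adjusted p = 0.616), with Cdkn1c at 1.5 and Cdkn2a at -1.99. Y-linked genes had too few tested members for a test.

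**Figure D2:**
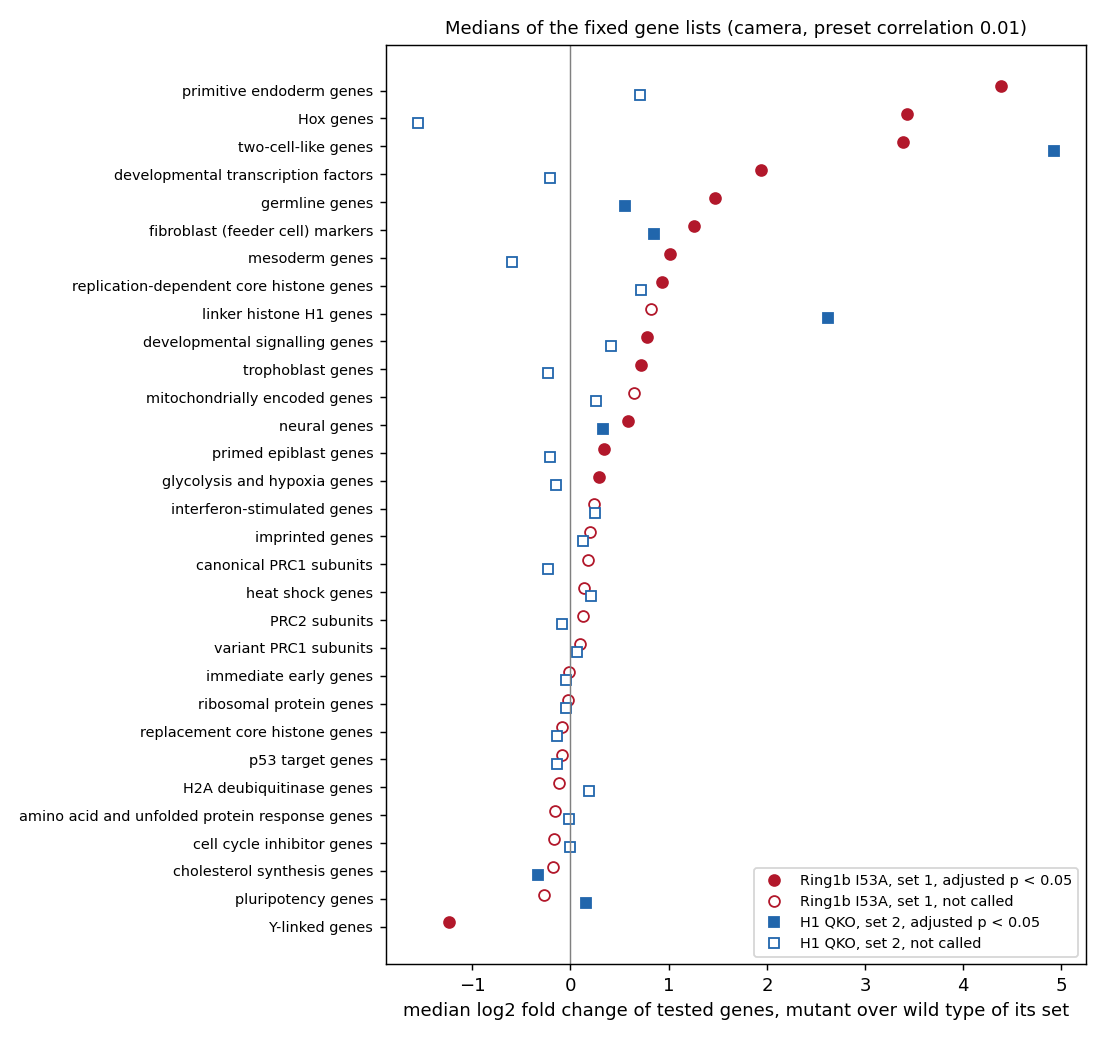
Median log2 fold change of the tested genes of each fixed list, for I53A over wild type (red circles) and for libraries labelled QKO over wild type (blue squares), with filled symbols where camera's adjusted p at the preset correlation was under 0.05 and open symbols where it was not. Primitive endoderm genes lie at 4.38 in I53A and 0.71 in the libraries labelled QKO, Hox genes at 3.43 and -1.56, and two-cell-like genes at 3.38 and 4.92. The tested members differ between the comparisons, with 20 Hox genes in I53A and 6 in the libraries labelled QKO.

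Setting both comparisons side by side asks whether the same genes change with the Ring1b mutation and under the QKO label. Zscan4d, Nes, Col1a2, Syce1 and Plk2 rose in both, and Nkx6-3, from 17.7 to 1.51 CPM in set 1 and from 4.84 to 0.405 CPM in set 2, each scaled within its set, and H2afy2 fell in both. Of 14589 genes tested in both, 1102 were called higher in both (693 expected for independent calls, odds ratio 2.47, Fisher's exact test with Benjamini-Hochberg adjustment over the 4 directions, adjusted p = 1.4e-83). Another 1138 were called lower in both (802 expected, odds ratio 1.99, adjusted p = 1.3e-52). Opposite calls were fewer than expected, with 500 genes higher in I53A and lower in the libraries labelled QKO (731 expected, odds ratio 0.550) and 624 the other way (760 expected, odds ratio 0.724), at adjusted p = 1.2e-30 and 5.4e-11. Of the genes called in both, 66.6% changed in the same direction, and with the replicate block 3473 genes shared a direction in place of 2240. Across genes the log2 fold changes correlated at Pearson's r = 0.324 and Spearman's rho = 0.202, and genes are not independent replicates. The comparisons share no libraries.

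The difference between the effects, I53A minus the libraries labelled QKO, had the lowest p for Slfn9 among the genes named, which fell in I53A (-4.78) and rose in the libraries labelled QKO (3.77). Its difference was -8.53 ± 0.23 on the log2 scale (edgeR adjusted p = 3.3e-12). With scaling over all 12 libraries Slfn9 stood at 20.4 CPM in wild type of set 1 and 0.734 CPM in I53A. It stood at 1.79 CPM in wild type of set 2 and 24.6 CPM in the libraries labelled QKO. The wild type groups thus started from different levels of Slfn9, and the libraries labelled QKO stood near wild type of set 1. Beyond Slfn9, the rule named genes with next to no counts in some group, for which counts are given. Hoxa7 had 5 counts in wild type and 140 in I53A, and 16 in wild type and 1 in the libraries labelled QKO (edgeR adjusted p = 6.4e-05 for the difference). In the same order Lgi1 had 40, 12, 0 and 266 counts (edgeR adjusted p = 4.6e-06), Maml2 46, 34, 0 and 90 (0.000223), Slfn3 49, 38, 0 and 61 (0.000761) and Xlr5c 80, 11, 0 and 7 (0.00173). Lgals2 had 0, 159, 7 and 4 counts (edgeR adjusted p = 0.000525), the growth factor gene Igf1 2, 150, 5 and 1 (0.000739), Hoxa3 1, 66, 10 and 3 (0.000464) and Hoxa5 7, 60, 4 and 0 (0.0252). EdgeR lost the call of Hoxa5 without wild type replicate 1 or 2 of set 2 (adjusted p = 0.0869 for each). Hoxa3 and Hoxa5 overlap each other, and the Slfn and Xlr families have close copies.

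Over all genes, 5961 of 16501 differed between the effects, 2968 with the greater value in I53A and 2993 with the lower. Camera called the lists of primitive endoderm (median difference 3.44, adjusted p = 4.9e-37) and Hox genes (4.00, adjusted p = 1.3e-06), both of which held with an estimated correlation (adjusted p = 0.000327 and 0.00590). Of 20 primitive endoderm genes 17 had the greater value in I53A and 1 the lower (18 and 1 adjusted over the list alone), and of 20 Hox genes 15 and none (17 and none adjusted over the list alone). Only 6 Hox genes passed the filter in set 2 alone, so most of them had few reads there. Members that passed the filter of this fit only through I53A reads have the sign of their difference set by the filter. Another 9 lists were called at the preset correlation and are given in the closing section. Genes of the two-cell-like list were not among the lists called (median difference -1.40, camera adjusted p = 0.212).

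Whole chromosomes also shifted. In the libraries labelled QKO the genes of chromosome 14 had a median log2 fold change of 0.50, with 395 of 551 higher and 39 lower (camera adjusted p = 4.9e-21, and 0.0327 with an estimated correlation). All 9 windows of 10 Mb with at least 20 genes had medians above 0, from 0.38 to 0.69, and 85.8% of the genes were positive. Of the genes named above for this comparison, Pou4f1, Lgals3, Bap1 and Rpl15, which rose, and Gata4, which was not called (-0.56), lie on chromosome 14. In I53A, chromosome 8 genes had a median of -0.40, with 398 of 815 lower and 60 higher (camera adjusted p = 5.4e-10, and adjusted p = 0.0617 with an estimated correlation). Its 12 windows ranged from -0.51 to -0.24, and of the genes named above for I53A, Nkx6-3, Rbl2 and Sc4mol, which fell, and Col4a1 and Col4a2, which rose, lie on it. Chromosome 14 had a median of -0.21 in I53A, with 164 of 517 lower and 52 higher (camera adjusted p = 0.00971, and adjusted p = 0.0733 with an estimated correlation), while Gata4 and Sox7, which lie on it, rose.

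Chromosome 1, which holds Rnf2, was not called as a whole in I53A (median 0.11, camera adjusted p = 0.482), but its parts differed. The 421 genes proximal to Rnf2 with enough reads had a median of 0.20, and the 181 distal genes a median of -0.28, with 29.0% and 76.2% of them below 0. Of the genes named above for I53A, Usp21, which fell, and Mael and Atf3, which rose, lie on the distal part, and Nrp2, which fell, and Sox17 and Inhbb, which rose, on the proximal part.

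**Figure D3:**
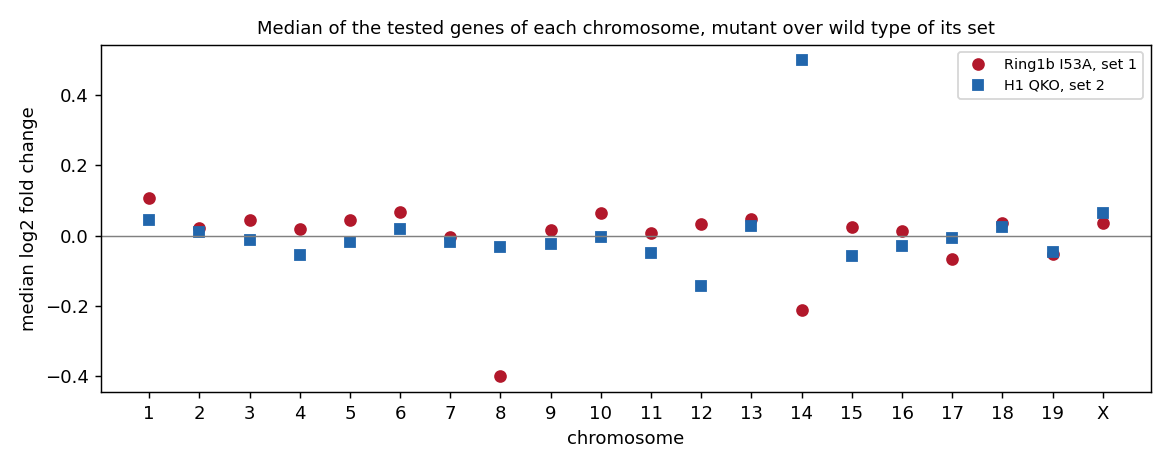
Median log2 fold change of the genes of chromosomes 1 to 19 and X, for I53A over wild type (red circles) and libraries labelled QKO over wild type (blue squares). Chromosome 14 lies at 0.50 in the libraries labelled QKO and at -0.21 in I53A, and chromosome 8 at -0.40 in I53A.

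**Figure D4:**
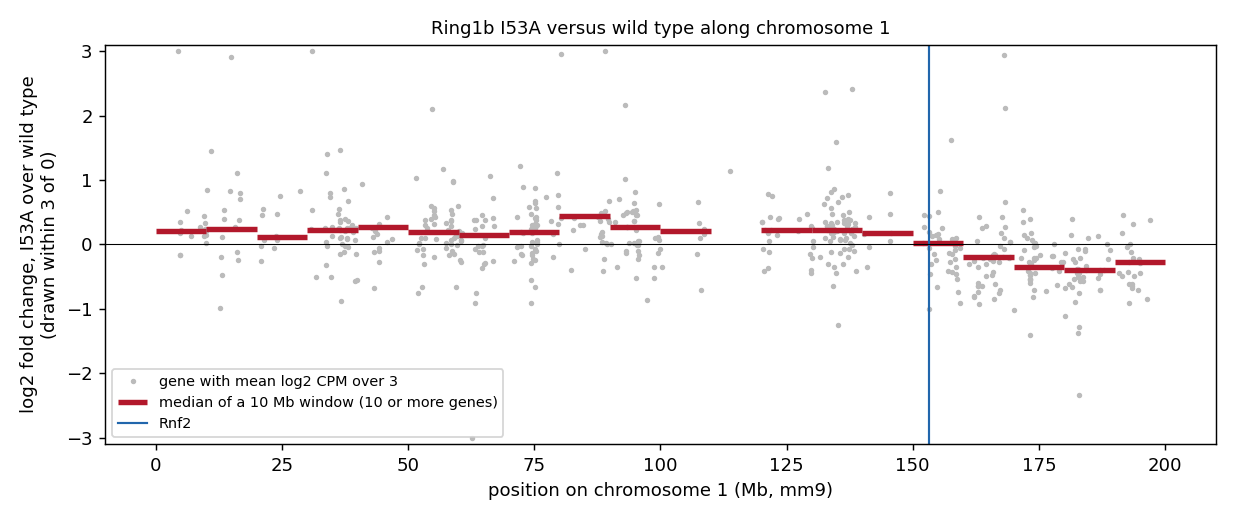
Log2 fold change of I53A over wild type for genes along chromosome 1 (position in Mb, mm9), with each gene as a grey point drawn within 3 of 0, medians of 10 Mb windows with 10 or more genes as red bars and Rnf2 as a blue line. Medians turn from 0.19 to -0.30 near 157.6 Mb, while Rnf2 lies at 153.3 Mb.

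The wild type groups of both sets were compared to see how far values can be read across sets. Ribosomal protein genes stood far higher in set 2, with 69 of 82 higher and 4 lower (median 4.58, camera adjusted p = 3.8e-137, and 0.000509 with an estimated correlation). With scaling over all 12 libraries Rpl31 stood at 10.1 ± 0.718 CPM in set 1 and 568 ± 14.6 CPM in set 2, and Rpl7 at 144 ± 4.29 and 2011 ± 21.8 CPM, while Rpl8 stood at 1691.7 ± 87.0 and 1908.8 ± 31.8 CPM. Gapdh, a glycolytic enzyme gene, stood at 18.96 ± 9.07 and 383 ± 24.5 CPM. The two-cell-like genes were lower in set 2 for all 11 members (median -5.14, camera adjusted p = 6.8e-07, and adjusted p = 0.156 with an estimated correlation), and all 6 Y-linked genes were lower (median -6.90, camera adjusted p = 1.2e-10, and 0.00635 with an estimated correlation). Camera called 9 lists, 7 of them higher in set 2, and 7 of the 9 held with an estimated correlation. EdgeR called 4615 genes higher and 4858 lower in set 2. With scaling by library size only, the median of all genes shifted by -0.17 on the log2 scale and the calls became 3323 higher and 6584 lower. Per the file headers, the alignments counted for set 1 carry TopHat and unique in their names and those of set 2 carry neither. Changes with genotype are therefore reported within a set. The tests between the wild type groups serve only to show how far the sets differ.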

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

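Among the tests below, those chosen only after the result was seen were the lower quartile and the share of genes on chromosome 14, the change point on chromosome 1 and the 3 tests on primitive endoderm genes.

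The effects of I53A and of the label QKO differed on chromosome 14 (median difference -0.66, camera adjusted p = 1.8e-19, and 2.6e-05 with an estimated correlation), chiefly because its genes were higher in the libraries labelled QKO. A bias by gene length is argued against, since the median was 0.52 after a gene-length offset and 0.50 without it. The rise was not limited to a small share of its genes, since 86.4% lay above the median of the other chromosomes. That share restates what had been seen and tests no cause beyond it. An extra copy of chromosome 14 in part or all of these cells stays open, since the lower quartile of its genes, 0.26 above the median of the other chromosomes (95% bootstrap interval 0.214 to 0.288), follows from shares already seen. DNA was not analysed here, and all 3 libraries carry the same label, so genotype and cell line history cannot be told apart.

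On chromosome 1, which holds the mutated gene, distal genes were lower than proximal genes in I53A. The step was -0.50 (95% bootstrap interval -0.61 to -0.42), and it was -0.50 after a gene-length offset, which argues against length bias. It was -0.50 in the first naming style and -0.49 in the replicate 3 pair, so neither style alone accounts for it. Each style holds both genotypes, so a run difference between genotypes within a style was not tested. The best change point lay at 157.6 Mb (interval 152.2 to 158.4 Mb), a range that holds Rnf2 at 153.3 Mb, but the values on either side of Rnf2 had been seen before. A change in copy number that begins near the edited gene therefore stays open, and DNA was not analysed here. The proximal genes had a median of 0.20, where all tested genes of the other chromosomes had -0.007. A change of the distal part alone would not shift the proximal part, so it would not account for the whole pattern.

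Primitive endoderm genes differed between the effects (median difference 3.44, camera adjusted p = 4.9e-37, and 0.000327 with an estimated correlation), with 17 of 20 greater in I53A and 1 lower. The median was 4.40 in the first naming style and 4.37 in the replicate 3 pair, so neither style alone accounts for the rise. Both genotypes are in each style, so a run difference between genotypes within a style was not tested. Of 12 further endoderm markers whose values had not been seen when they were listed, 8 were called higher and 2 lower (66.7%), and with 8 others seen before it was 16 of 20 (80%), so endoderm-like cells in the I53A cultures cannot be told apart from a rise of single genes, because the share lies between the bounds of 75% and 50% set for the test. Abundant members such as Lama1 (79.1 to 830 CPM) and Lrp2 (58.1 to 323 CPM) rose, but Nid1 (-0.28) and Apom (-1.44) fell, and 5 of the endoderm list are also developmental transcription factors. Whether the rise is part of a broader rise of developmental regulators stays open. Of 74 such genes outside the list 51 were higher (68.9%, against 18.1% of all genes), but they come from lists already seen. Members with next to no reads in wild type passed the filter only through I53A reads, which set their direction. That share is therefore partly fixed by the filter and is not a like match for the share of all genes.

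The other results stood out because the effects of I53A and of the label QKO differed in a test of the difference itself. Hox genes differed by a median of 4.00 (camera adjusted p = 1.3e-06, and 0.00590 with an estimated correlation). Hox genes, developmental regulators and lineage markers with next to no reads in the other groups passed the filter only through I53A reads. The filter set the sign of the difference for such members. Developmental transcription factors differed by 1.43 (camera adjusted p = 2.9e-05, and 0.130 with an estimated correlation). Germline genes differed by 0.58 (camera adjusted p = 2.9e-05, and 0.0521 with an estimated correlation). Mesoderm genes differed by 1.47 (camera adjusted p = 0.00243, and 0.130 with an estimated correlation). Trophoblast genes differed by 0.80 (camera adjusted p = 0.00169, and 0.0749 with an estimated correlation). Pluripotency genes differed by -0.28 (camera adjusted p = 0.000799, and 0.0521 with an estimated correlation). Linker histone genes differed by -2.17 (camera adjusted p = 0.00199, and 0.0521 with an estimated correlation). Canonical PRC1 subunits differed by 0.64 (camera adjusted p = 0.0145, and 0.130 with an estimated correlation). Glycolysis and hypoxia genes differed by 0.46 (camera adjusted p = 6.8e-06, and 0.0602 with an estimated correlation). Cholesterol synthesis genes differed by 0.20 (camera adjusted p = 0.0164, and 0.0718 with an estimated correlation). Levels of the glycolysis and hypoxia list and of the cholesterol synthesis list also differed between the wild type groups. Chromosome 8 differed by -0.36 (camera adjusted p = 4.2e-06, and 0.00120 with an estimated correlation).

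In all, 5961 genes differed between the effects. Of 100 splits of the libraries within the sets, 1, the real one, called as many, and the highest other called 2787. Splits that mix genotypes in both sets call next to no genes, so this excludes only that the groups do not differ at all, and does not test whether the effects differ more than unrelated effects would. The number of lists (11 called, highest other 13) was matched by 16 of the 100 splits and that of chromosomes (2 called, highest other 3) by 38. The other splits keep part of the difference between genotypes, and some hold the real split of a set. These numbers therefore neither exclude chance nor point to it.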

How the results depend on the processing

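The fits on replicates 1 and 2 of set 1 only, the block with exchanged numbers, the fits without whole chromosomes and the fits of wild type groups without each library were chosen only after the result was seen. The only result whose direction changed with a call in either fit was chromosome 16 in I53A (median 0.0137), which camera placed lower without a call (adjusted p = 0.944) and fry called higher (adjusted p = 0.00447). The causes of the changes given here were not tested except where fewer genes or libraries account for them. Of 5512 genes called in I53A, 5504 were also called with the replicate block, which called 8798, and the block with I53A replicates 1 and 2 exchanged called 8410. The block with a gene-length offset called 8850, a term for the naming style 8821 and replicates 1 and 2 only 8343. In set 2, where the condition for the block was not met, it called 9080 genes in place of 8903. Requiring a 2-fold change left 1868 genes in I53A, 1841 in the libraries labelled QKO, 2229 for the difference and 430 with a shared direction, by construction. Shared directions rose from 2240 to 3473 with the block and 3471 with block and offset. Across genes Pearson's r fell to 0.235 without a filter, and Spearman's rho was 0.195 with the filter of 1 CPM and 0.215 without chromosomes 1, 8, 14 and Y.

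With an estimated correlation camera called 4 lists in I53A, 1 in the libraries labelled QKO and 0 chromosomes in I53A, in place of 14, 7 and 2. The rotation test fry, which does not compare a set with other genes, called 26 and 25 lists, and 18 and 12 chromosomes. Leaving out 1 library at a time gave 3828 to 5917 genes in I53A, 8071 to 8743 in the libraries labelled QKO, 5090 to 6573 for the difference, 8597 to 10046 between wild type groups and 1615 to 2342 with a shared direction. Pearson's r ranged from 0.299 to 0.336 and Spearman's rho from 0.185 to 0.209. Lists ranged from 12 to 15 in I53A and from 7 to 9 in the libraries labelled QKO, and chromosomes stayed at 2 and 1. Without chromosomes 1, 8, 14 and Y, 4426 genes were called in I53A and 4820 for the difference, and without chromosome 14 8469 in the libraries labelled QKO, since fewer genes were tested. DESeq2 called 5655, 8096 and 6141 genes for I53A, the label QKO and the difference.

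For single named genes, 1823 values under alternatives were unchanged as to the call in I53A and 11 lost the call, with 1328 and 1 in set 2 and 197 and 2 for the difference. For lists, 422 were unchanged, 22 gained and 20 lost a call in I53A, with 386, 28 and 6 in set 2. For chromosomes, 262 were unchanged, 15 gained and 2 lost a call and 1 reversed in I53A, and 249 were unchanged and 11 gained in set 2. Depth limits the genes with next to no counts, for which only bounds or counting intervals are given.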

Other observations

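The 3 non-coding RNAs of the Dlk1-Dio3 region that fell in I53A are given here for all 4 groups. With scaling over all 12 libraries, which gives other values than scaling within a set, Meg3 stood at 55.5 ± 5.21 CPM in wild type and 0.880 ± 0.124 CPM in I53A, and at 0.153 ± 0.0471 CPM in wild type of set 2 and 0.0314 ± 0.0272 CPM in the libraries labelled QKO (n = 3 each). In the same order Rian stood at 69.4, 0.718, 0.629 and 0.366 CPM, and Mirg had 429, 6, 0 and 2 counts. Of the Y-linked genes, Uty stood at 20.1, 4.55, 0.299 and 0.0366 CPM and Ddx3y at 35.4, 12.3, 0.168 and 0.0432 CPM. Levels of some genes differed greatly between the wild type groups, so these values are given without a test between I53A and set 2.

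The two-cell-like genes were lower in wild type of set 2 than in wild type of set 1 for 11 of 11 members, with a median difference of -5.14 on the log2 scale. The libraries labelled QKO lay nearer to wild type of set 1, with a median difference of -0.33 from it and 7 of 11 members lower. With scaling over all 12 libraries Zscan4d stood at 17.5 ± 4.04 CPM in wild type of set 1, 183 ± 21.7 CPM in I53A, 0.421 ± 0.204 CPM in wild type of set 2 and 16.6 ± 2.32 CPM in the libraries labelled QKO. This comparison of medians was chosen only after the result was seen.

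The calls were also counted for other splits of the same libraries, each of which mixes genotypes. With 6 libraries there are 10 splits, too few for a share under 0.05. For I53A the real split called 5512 genes and the highest other 1, for the label QKO 8903 and 0, and for the wild type groups 9473 and 0, so that 1 of the 10 splits reached the real value in each. The real split called 14 lists in I53A, where the highest other called 14 and 2 of 10 splits reached the real value, and 7 lists under the label QKO, where the highest other called 8 and 2 of 10 reached it. It called 2 chromosomes in I53A, where the highest other called 2 and 4 of 10 reached it, and 1 chromosome under the label QKO, where the highest other called 1 and 10 of 10 reached it. The other splits hold unequal numbers of each genotype in their parts, so part of a shift shared by many genes stays in them. These counts of lists and chromosomes therefore neither exclude chance nor point to it. In set 1, the 3 other splits that part every replicate pair called 0 genes by edgeR and 7, 12 and 12 lists. For genes called in both comparisons in the same direction, 1 of 100 pairs of splits, the real one with 2240 genes, reached that count and the highest other shared 0. Splits that mix genotypes call next to no genes, so this excludes only that the groups do not differ at all, and does not test whether the shared direction exceeds that of unrelated changes.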
